A study of Homo sapiens with 2 samples.

How the data were processed

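Peripheral blood mononuclear cells (PBMCs, the lymphocytes, monocytes, dendritic cells and related cells left after density separation of blood) of a single human donor were divided over 2 single-cell RNA sequencing technologies. The 3' GEM-X assay captures cells in droplets on a microfluidic chip, and PIPseq V captures them with barcoded beads by vortex mixing. Each technology has 1 library. For PIPseq V the deposited files hold a matrix of UMI counts per gene and cell barcode, a barcode list and a gene list; a UMI (unique molecular identifier) marks a captured molecule, so PCR copies are counted once. For 3' GEM-X the barcode list and the gene list were used, and its count matrix was not analysed here. No expression value was therefore compared between the technologies.

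The deposited counts are whole numbers with no normalization, as their values show. The submitters' processing notes name bcl2fastq, Cell Ranger 8 and the human build hg38 for both libraries, without saying which tool made which file. The tool that counted the PIPseq V reads, the way barcodes were selected and the annotation release are not given in the sources used here. No barcode had fewer than 1042 UMIs, so shallow barcodes were already absent from the deposited matrix.

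Barcodes with at least 300 genes and at most 20% mitochondrially encoded UMIs were kept, which left 18362 of 18489. Doublets were marked with Scrublet as run by scanpy 1.11.5, with 2 simulated doublets per cell and an expected rate of 5%. The automatic threshold of 0.324 marked 117 barcodes (0.637%), just over the planned minimum of 0.5% for using the calls, and 46.6% of the simulated doublets lay above it, so doublets remain among the kept cells. The 18245 cells left held 76690850 UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes gave 30 principal components. A graph of 15 nearest neighbours weighted by shared neighbours was clustered with leidenalg 0.10.2 at resolution 1, which gave 24 clusters. The members of all function lists were left out of the variable genes, so that they do not define the clusters. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9.

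Clusters were named from 19 marker lists and are called "-like" for that reason. A list's score in a cluster was the mean of its markers' CPM, each relative to the highest cluster. A name needed a score of 0.4, 3 detected markers and no more leading genes from another list than from its own; otherwise the cluster stayed unnamed. These scoring thresholds, unlike the markers, were set after clusters had been seen. Another implementation of the doublet scheme was used in a preliminary look, and it is now an alternative setting: it marked 187 barcodes, 71 of them shared. A scan for short sequence motifs in ribosomal protein transcripts, made after the result was seen, found no clear motif and is not reported further. Annotated 3' ends of those genes can be implausibly long (RPL37 at 7686 bases), so coding sequences of principal isoforms were used for UpA number and length. The share of each class has an exact Clopper-Pearson 95% interval. To compare genes per cell across depths, each cell was thinned to 1600 UMIs, which left out 1597 shallower cells.

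UMIs were summed per class and expressed as CPM (counts scaled to the same UMI total in each class), with exact Poisson 95% intervals. Ratios between classes have the exact conditional binomial 95% interval. With 1 library, cells are not replicates, so no test, p-value or genome-wide count of changed genes was made, and all intervals cover counting error only. The marker lists, the 6 contrasts of cell classes, the 20 function lists and 15 of the 19 alternative settings were fixed before the data were examined. A list member was measured where it had at least 20 UMIs and 10 CPM in at least 1 of the 2 classes, and a ratio was named by size, at least 2-fold. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a percentile that describes this library. For each list and contrast, up to 2 members with the highest and up to 2 with the lowest ratio past 2-fold were taken, at most 30 genes per contrast, with lists ordered by the distance of their median from 0. Genes with near-identical copies that can share reads (XCL1 and XCL2, CCL4 and CCL4L2, HSPA1A and HSPA1B, HBG1 and HBG2, and the GAGE family) have uncertain separate values. Gene IDs were matched to GENCODE 29 for biotypes, and 92.0% of IDs, holding 99.5% of UMIs, had an entry. A further part of the test for cells of an erythroleukaemia line is not reported here.

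The contrast calculation was checked on simulated counts. Both simulated classes were Poisson draws from the summed counts of the second class of a contrast, at the real UMI totals. The most abundant genes were left unchanged. The check therefore covers counting error only and not the shifts in makeup between real classes. For classical monocyte-like over T-like, with 8126 genes in the step, 100 of 100 genes changed 4-fold passed the 2-fold limit and 0 of 100 changed 1.5-fold did. The interval held the true ratio for 98% of the former and 94% of the latter. For NK-like over T-like, the smaller class, 7 of 8086 unchanged genes passed 2-fold.

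The alternatives covered the cell filter, doublets, cluster resolution, variable genes, scaling, means over cells, minimum levels, free RNA and gene matching. Those added after seeing the data were the other doublet implementation, counting an immunoglobulin-led cluster as B-like, leaving out the largest classical monocyte-like cluster, and adding a GZMH-led cluster to the CD8 T-like class. Depth sets the precision: the T-like class sums 37847612 UMIs and the NK-like class 2226103, so a gene at 10 CPM rests on far fewer UMIs in the latter.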

Results

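PBMCs of a single donor were profiled with 2 single-cell technologies, 3' GEM-X and PIPseq V, with 1 library each, so differences had no replicate check. The PIPseq V matrix held 18489 barcodes, 77602688 UMIs and 32068167 nonzero entries. Depth per barcode ranged from 1042 to 32938 UMIs, with a median of 3782. Of the 37468 genes listed, 33536 had at least 1 UMI.

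The study compares the technologies on cells of the same donor. The 3' GEM-X list held 18058 barcodes, 0.977 times the PIPseq V number. The gene lists were nearly the same: 37344 gene IDs were listed for both, 124 for PIPseq V only and 1262 for 3' GEM-X only, and 535 of the shared IDs carried another symbol. The shared genes took 99.6% of PIPseq V UMIs, and 335646 UMIs fell on genes listed for PIPseq V only. Matched by symbol, 36805 were shared. Expression in the 3' GEM-X library was not analysed here.

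In the 18245 kept PIPseq V cells, T-like cells were the largest class, with 8650 cells or 47.4% (95% Clopper-Pearson interval 46.7 to 48.1). Classical monocyte-like cells made up 26.9% (26.2 to 27.5; 4905 cells) and B-like cells 13.6% (13.1 to 14.1; 2485 cells). NK-like cells were 2.48% (2.26 to 2.72), nonclassical monocyte-like cells 2.19%, conventional DC-like cells 1.39%, platelet-like barcodes 0.707%, plasmacytoid DC-like cells 0.181% and progenitor-like cells 0.137%. Within the T-like class, CD4 T-like cells were 21.9% of all cells, CD8 T-like 7.91%, MAIT-like 3.03% and Treg-like 1.06%, and 13.5% took no subclass. That last part includes a cluster of 1226 cells (6.72% of all cells) with GZMH and CD8A among its leading genes. That cluster scored 0.649 on the CD8 T list and 0.0457 on the CD4 T list. The CD8 T list holds only 3 markers, so the rule of 3 detected markers required all of them, and this kept the cluster out. The CD8 T-like share would be higher with that cluster counted in it. Clusters that no marker list named held 4.999%. They include a cluster with B-cell markers led by immunoglobulin genes, which, counted as B-like, brings that class to 16.03%.

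**Figure D1:**
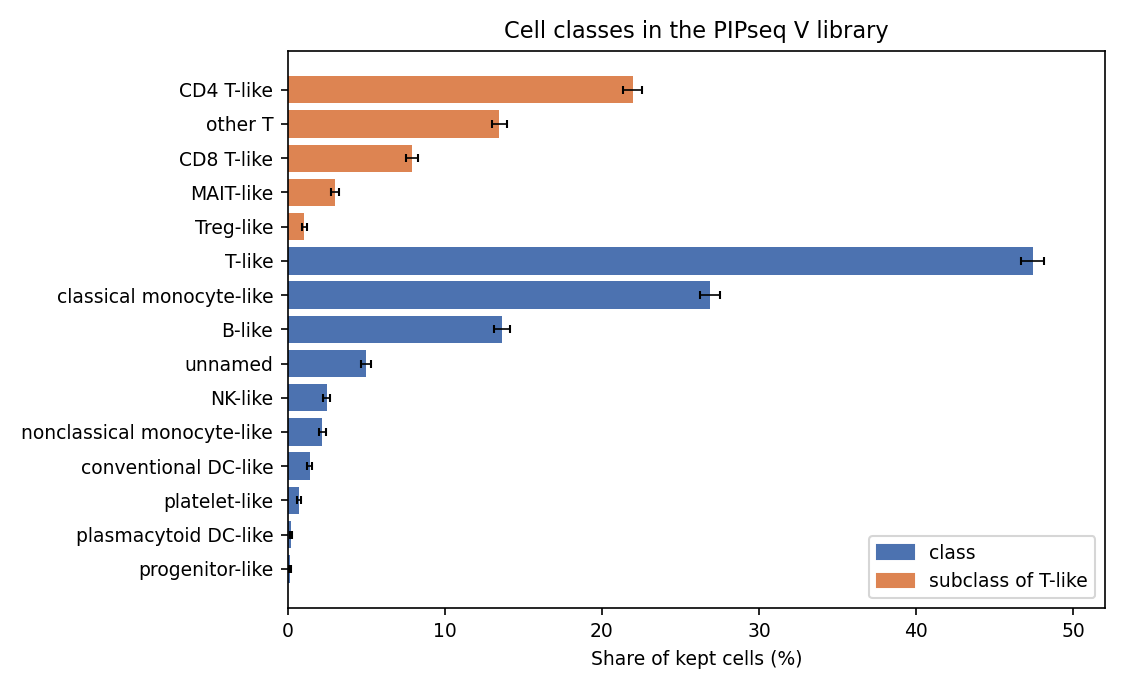
Share of kept PIPseq V cells (x axis, percent) in each class (blue bars) and in each subclass of T-like cells (orange bars), with 95% Clopper-Pearson intervals as error bars. T-like cells reach 47.4%, classical monocyte-like cells 26.9% and B-like cells 13.6%.

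Cell classes differed in depth and in transcript makeup. A median T-like cell had 4166.5 UMIs, a B-like cell 4505, an NK-like cell 4588 and a classical monocyte-like cell 2728, whereas conventional DC-like cells had 8746. Thinned to 1600 UMIs, classical monocyte-like cells showed a median of 1081 genes against 856 in T-like cells, a ratio of 1.26; without thinning the medians were 1591 and 1578.5 genes, a ratio of 1.01. Thinning left out 705 T-like and 588 classical monocyte-like cells as too shallow. Ribosomal protein genes took a median of 28.7% of UMIs in T-like cells, 21.1% in B-like cells, 15.05% in NK-like cells and 4.36% in classical monocyte-like cells. Mitochondrially encoded UMIs were 4.81% in T-like and 2.32% in classical monocyte-like cells. Over all kept cells, protein-coding genes took 89.6% of UMIs, noncoding genes 5.48% and mitochondrial genes 4.18%.

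Free RNA set a background whose size relative to the source cells differed between genes. LYZ, the lysozyme gene of myeloid cells, stood at 1248 CPM in classical monocyte-like cells and at 37.6 CPM in T-like, 34.1 in B-like and 33.7 in NK-like cells. A LYZ UMI was seen in 13.0% of T-like cells, at a median depth of 4166.5 UMIs, and in 69.9% of classical monocyte-like cells, at 2728. S100A9, a calcium-binding alarmin, was at 5388 CPM in classical monocyte-like and 32.5 in B-like cells. S100A8 was at 160 CPM in classical monocyte-like, 16.8 in T-like and 15.6 in B-like cells. Its background thus lay closer to its monocyte-like level than that of LYZ or S100A9. Of the lymphocyte genes, the B-cell receptor component CD79A was at 462 CPM in B-like and 4.31 in T-like cells, and the T-cell receptor component CD3E was at 353 CPM in T-like and 4.13 in B-like cells. In NK-like cells CD3E was at 149 CPM and CD3D at 18.4 CPM (95% interval 13.2 to 24.99), both above their levels in B-like cells (4.13 and 2.63). Among the named classes, HBA1 was at 503 CPM in platelet-like barcodes and at most 8.54 CPM, in NK-like cells, elsewhere.

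Classical monocyte-like cells differed from T-like cells in receptors for antibody and complement, lysosome genes and MHC class II, which were higher, and in cytotoxic, ribosomal protein and mitochondrially encoded genes, which were lower. Of the 20 function lists, 7 had a median at least 2-fold higher and 10 at least 2-fold lower. All 8 measured Fc and complement receptor genes were at least 2-fold higher (median log2 ratio 4.92, above all matched random lists), among them ITGAX, an integrin that binds complement fragments, at 786 against 5.84 CPM (135-fold), and CD93, a phagocyte receptor, at 55.9-fold. Of 16 measured lysosome genes, 14 were higher by that margin and 0 lower (median 3.06). They included the lysosomal membrane glycoprotein gene CD68 (ENSG00000129226), at 882 against 4.25 CPM (log2 ratio 7.70, 95% interval 7.47 to 7.93), and the protease gene CTSZ (80.6-fold). MHC class II genes, which present peptides to CD4 T cells, were higher in 9 of 10 measured members (median 2.81), with HLA-DMB 32.0-fold and HLA-DRA 19.4-fold higher, while MHC class I genes were lower in 7 of 12 and higher in 1 (median -1.32). Among pattern recognition genes (6 of 11 higher, 1 lower), TLR4, the lipopolysaccharide receptor, was 141-fold higher and the lipopeptide receptor TLR2 71.8-fold higher.

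Some of the lower lists held members that went the other way. SRGN, a granule proteoglycan shared by leukocytes, was 3.10-fold higher, while the other 10 measured cytotoxic granule genes were at least 2-fold lower (list median -5.67), such as GZMA (68.4-fold) and CTSW (71.98-fold). CCL5 and CCL4, chemokines of effector lymphocytes, were 65.1-fold and 67.1-fold lower, whereas the neutrophil attractant CXCL8 was 25.6-fold and CXCL16 33.4-fold higher. The chemokine receptor CCR1 was 42.6-fold higher, and CCR6 and the sphingosine receptor S1PR5 were 50.8-fold and 55.6-fold lower. Of the cytokines, IL1B was 55.1-fold and the B-cell survival factor TNFSF13B 21.0-fold higher, and IFNG was 54.5-fold lower. Of 78 ribosomal protein genes, 72 were at least 2-fold lower (median -3.35, below all matched random lists), down to RPS18 at 142.5 against 6007 CPM (42.1-fold lower) and RPS26 (44.5-fold lower). Mitochondrially encoded genes were lower in 11 of 13, led by MT-ATP8 (23.5-fold) and MT-ATP6 (13.4-fold), both subunits of ATP synthase. Heat shock genes were lower in 7 of 9, including HSPA8 (10.5-fold) and HSPH1 (9.27-fold), and the cell cycle genes PCNA and STMN1 were 8.05-fold and 20.3-fold lower. STING1, a DNA-sensing adaptor, was 2.34-fold lower.

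In this contrast the median of all 10483 measured genes lay 0.40 above 0 on the log2 scale, and median-of-ratios scaling, which removes this shift, left 4 lists higher, as did CPM without mitochondrial and ribosomal protein genes and MALAT1. Without the largest classical monocyte-like cluster, 6 lists were lower, 21 of 28 named ratios moved over 1.5 times, STING1 turned to a log2 ratio of 0.66, MT-ATP6 lost the 2-fold call (-0.84 against -3.74) and RPS18 went from -5.40 to -1.93. Where the lower level lies near the free RNA, a fold is at best a lower limit. Free RNA was assumed to have the makeup of all kept cells and to be 5.36% of UMIs. That share was taken from LYZ, S100A8, S100A9 and VCAN in B-like cells. The background values above go against a single share for all genes. S100A8 was at 15.6 CPM in B-like and 160 in classical monocyte-like cells, and CD3E at 4.13 in B-like and 353 in T-like cells. The subtraction can therefore remove too much for some genes and too little for others. Subtracting free RNA on that assumption moved 23 of 30 named ratios away from 0 by over 1.5 times, ITGAX from 7.07 to 13.26 and CD68 from 7.70 to 13.42. The T-like counts of ITGAX and CD68 fell to 0 there and were set at a floor of 3 UMIs. Their ratios after subtraction are therefore set by that floor and were not measured.

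**Figure D2:**
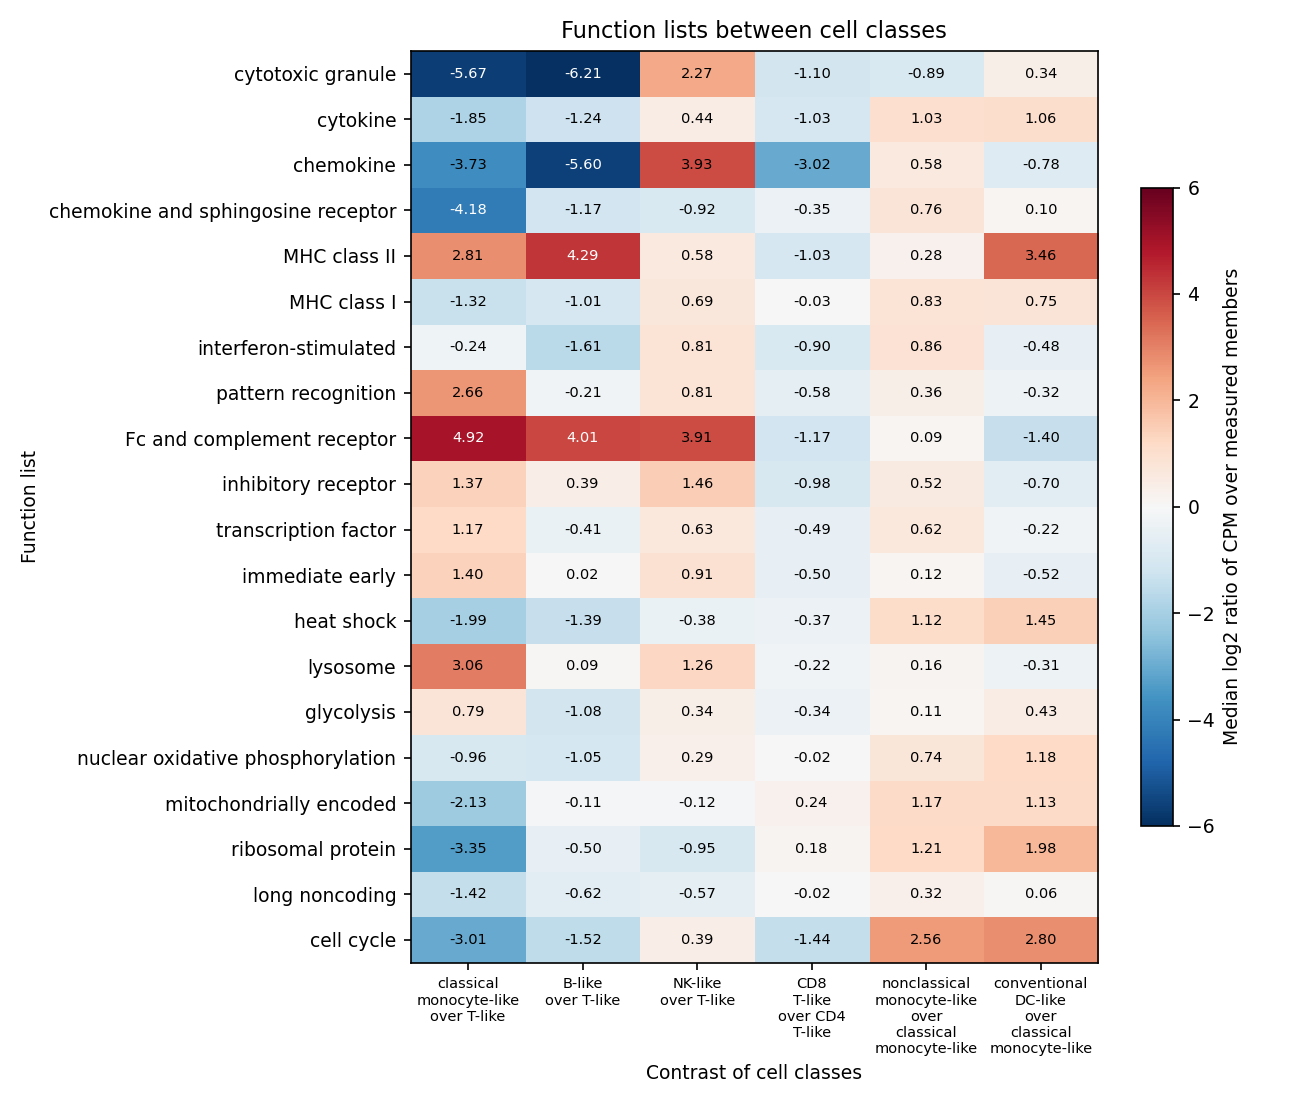
Median log2 ratio of CPM over the measured members (colour scale and printed numbers) of each function list (y axis) in each of the 6 contrasts of cell classes (x axis). Cytotoxic granule genes have medians of -5.67 and -6.21 in classical monocyte-like and B-like cells over T-like cells, and MHC class II genes 2.81 and 4.29.

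B-like cells differed from T-like cells by high antigen presentation and low cytotoxic, chemokine and interferon-stimulated gene levels. All 12 MHC class II genes were at least 3.85 higher on the log2 scale (median 4.29), with HLA-DQB1 (ENSG00000179344) at 537 against 6.95 CPM (77.2-fold; log2 ratio 6.27, 95% interval 6.09 to 6.45) and HLA-DMB 59.5-fold higher. Of 4 measured Fc and complement receptor genes, 3 were higher (median 4.01): the low-affinity IgE receptor FCER2 by 191-fold and the inhibitory IgG receptor FCGR2B by 23.4-fold, while the integrin ITGAM was 3.44-fold lower. These were the 2 lists with a median at least 2-fold higher, and 10 lists were lower. CXCR5, the receptor that guides B cells to follicles, was 12.7-fold higher, and S1PR1 and S1PR5 were 2.75-fold and 72.6-fold lower, the latter on 3 UMIs in B-like cells (log2 interval -8.46 to -4.63). IL6 was at 15.7 CPM in B-like cells and rested on 2 UMIs in T-like cells (log2 ratio 8.22, interval 6.34 to 11.27).

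All 11 measured cytotoxic granule genes were lower in B-like cells (median -6.21), among them the granzyme GZMH (107-fold) and the protease inhibitor CST7 (105-fold). The T-like level rests on a few clusters: 5094 of 6381 GZMH UMIs of T-like cells came from a cluster of 1226 cells, and a CD4 T-like cluster of 987 cells had GZMH at 0.762 CPM against 1.58 in B-like cells. CCL4 and CCL5 were 147-fold and 91.7-fold lower, and the cytokines IL32 and IFNG 116-fold and 74.8-fold lower. Interferon-stimulated genes were lower in 10 of 14 (median -1.61), with IFIT1 56.2-fold and IFIT3 39.0-fold lower. Of the T-like UMIs of these genes, 707 of 1121 and 3402 of 5188 came from a cluster of 736 cells, and in CD8 T-like cells IFIT3 was at 1.28 CPM against 3.51 in B-like cells. Of the heat shock genes, 6 of 9 were lower, DNAJB1 by 11.96-fold and HSPA8 by 6.76-fold. Glycolysis genes were lower in 8 of 16 and higher in 3 (median -1.08): the lactate dehydrogenases LDHA and LDHB were 4.98-fold and 9.18-fold lower, the glucose transporter SLC2A1 and hexokinase HK2 4.04-fold and 3.54-fold higher. Nuclear oxidative phosphorylation genes were lower in 39 of 72 and higher in 0 (median -1.05), including NDUFS5 (4.68-fold) and NDUFB7 (4.46-fold). Among MHC class I genes, 6 of 12 were lower, B2M by 3.04-fold and its transactivator NLRC5 by 3.42-fold. Of 4 measured cell cycle genes, the replication factor MCM5 was 2.14-fold higher and STMN1 and PCNA were 4.97-fold and 5.86-fold lower. The chemokine and sphingosine receptor median turned from -1.17 to 1.99 where genes needed 50 UMIs and 50 CPM, the number of higher lists ranged from 1 to 4, and subtracting free RNA moved 13 of 30 named ratios over 1.5 times. With the immunoglobulin-led cluster counted as B-like, 7 lists were lower and 5 of 30 named ratios moved over 1.5 times, PCNA from -2.55 to -1.48.

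NK-like cells differed from T-like cells by higher cytotoxic granule, lymphotactin and Fc receptor genes. Of 11 measured cytotoxic granule genes, 9 were at least 2-fold higher and 0 lower (median 2.27), led by GNLY (ENSG00000115523), a pore-forming granule protein, at 6559 against 295 CPM (22.2-fold; log2 ratio 4.48, interval 4.44 to 4.51), and perforin, PRF1 (13.9-fold). The lymphotactins XCL1 and XCL2, near-identical copies that attract dendritic cells, were 41.0-fold and 26.0-fold higher, and 4 of 5 chemokines passed 2-fold (median 3.93). All 4 measured Fc and complement receptor genes were higher, with the signalling chain FCER1G 83.0-fold and ITGAX 22.2-fold higher. In all, 5 lists were higher and 0 lower.

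Inhibitory receptors went both ways in NK-like cells, with 5 of 8 higher, such as CD244 (10.7-fold) and HAVCR2 (5.28-fold), and 2 lower, LAG3 (4.62-fold) and KLRG1 (2.56-fold). Lysosome genes were higher in 9 of 15 (median 1.26), including CD63 (6.46-fold) and CTSD (5.74-fold). S1PR5 and CX3CR1, receptors of circulating effector cells, were 11.3-fold and 7.39-fold higher; CCR6 was 31.1-fold lower on 2 UMIs (log2 interval -8.01 to -3.10). Of the transcription factors, IRF8 was 18.5-fold and NFIL3, required for NK development, 6.52-fold higher, KLF2 was 2.36-fold lower, and ID3 was 82.2-fold lower on 1 UMI (log2 interval -11.7 to -3.88). The immediate early genes EGR1 and IER3 were 7.29-fold and 3.84-fold higher, and the innate sensors TLR1 and NOD1 4.12-fold and 2.19-fold higher. Interferon-stimulated genes were higher in 6 of 16, including SAMD9L (2.94-fold) and IRF7 (2.64-fold), and MX2 was 2.28-fold lower. The peptide-loading genes TAP1 and TAPBP were 2.38-fold and 2.30-fold higher. Ribosomal protein genes were lower in 29 of 78 (median -0.95), RPL36 by 2.51-fold and RPS12 by 2.37-fold. The median of all measured genes lay 0.34 above 0, and with median-of-ratios scaling 2 lists were lower. CPM without the abundant genes left 3 lists higher, and a minimum of 10 UMIs and 1 CPM left 2; subtracting free RNA moved 7 of 30 named ratios over 1.5 times.

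The CD8 T-like class was a single cluster of 1444 cells led by LINC02446, NELL2 and LEF1, genes of naive T cells, while the 3 CD4 T-like clusters together held 4004 cells. The naming rule left the cluster with GZMH and CD8A among its leading genes out of the CD8 T-like class. The contrast therefore mixes lineage with cell state, and its ratios cannot be read as differences between CD8 and CD4 T cells in general. Relative to CD4 T-like cells, 6 lists had a median at least 2-fold lower and 0 higher: cytotoxic granules (4 of 8 members lower, 1 higher), cytokines (5 of 8 lower), MHC class II (3 of 6), cell cycle (3 of 4), and chemokines and Fc and complement receptors, which rest on a single measured gene each, CCL5 and CR1. CCL5 was 8.10-fold lower, the granzyme GZMK 21.2-fold and CST7 9.85-fold lower, while CTSW, a protease of CD8 T and NK cells, was 3.59-fold higher. CCR6, a receptor of mucosal homing cells, was at 0.571 against 31.9 CPM (55.9-fold lower; log2 ratio -5.81, interval -7.69 to -4.44). Interferon-stimulated genes were lower in 6 of 13 and higher in 0, with IFIT3 28.9-fold and IFIT1 20.5-fold lower, where 484 of the 636 IFIT3 UMIs of CD4 T-like cells came from a cluster of 1690 cells. The transcription factors PRDM1 and TOX, linked to effector and chronic activation states, were 23.2-fold and 4.88-fold lower, and the checkpoint receptors CTLA4 and KLRG1 10.2-fold and 2.92-fold lower. TNF was 19.7-fold and TNFSF10 3.42-fold lower, HLA-DRB1 4.405-fold and HLA-DPA1 2.51-fold, the proliferation gene TOP2A 10.3-fold and PCNA 3.40-fold. Smaller ratios were those of CGAS (2.99-fold lower), IFIH1 (2.34-fold), HSPA1A (2.68-fold), CTSB (2.71-fold), CR1 (2.25-fold) and the noncoding RNA MIAT (2.67-fold). Ribosomal protein and mitochondrially encoded genes lay within 2-fold in all members, with medians of 0.18 and 0.24. The list calls depend on the settings: resolution 0.5 left 1 lower list, resolution 2 left 2 and a minimum of 50 UMIs and 50 CPM left 1, and the cytotoxic median turned to 0.67 at resolution 0.5 and to 0.71 with that minimum. Adding the T-like cluster of 1226 cells led by GZMH and CD8A to the CD8 T-like class gave 4 lists higher and 0 lower and turned CCL5 to a log2 ratio of 3.15 and CST7 to 3.65. Of the 23 named genes, 6 stayed past 2-fold on the same side in every setting that measured them: CTSW, CCR6, CTLA4, TOP2A, CR1 and CTSB. Resolution 0.5 measured only 8 of the 23 named genes, and the minimum of 50 UMIs and 50 CPM measured 3. Of the 8 ratios at resolution 0.5, 7 moved by more than the margin used in the other contrasts. CTLA4 and TOP2A were each measured in 9 settings and CTSW in 13, so the 6 genes were not tested equally.

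Nonclassical monocyte-like cells, which carry FCGR3A and CDKN1C, differed from classical monocyte-like cells by higher ribosomal protein, mitochondrially encoded, heat shock, cytokine and cell cycle list medians, 5 lists in all, with 0 lower, the cell cycle list resting on 2 measured genes of 12. MS4A7, another marker on the nonclassical list, was at 0 CPM in every class, and whether this library counts it was not tested. OAS1, an interferon-stimulated antiviral enzyme (ENSG00000089127), was at 48.7 against 5.71 CPM (8.52-fold; log2 ratio 3.09, interval 2.69 to 3.50), and IRF7 was 5.29-fold higher; 7 of 16 interferon-stimulated genes passed 2-fold and 0 were lower. The transcription factors KLF4 and KLF2 were 8.55-fold and 4.96-fold higher, and NFIL3 and TOX 3.004-fold and 3.65-fold lower. TNF and LTB were 3.23-fold and 5.58-fold higher, and AREG and TGFB1 5.61-fold and 2.29-fold lower. The inhibitory receptor LILRB1, which binds MHC class I, was 4.69-fold higher, as were HLA-F (4.38-fold), the proteasome subunit PSMB8 (4.46-fold) and the receptor CXCR4 (3.55-fold), while CCR1 was 4.25-fold lower. The heat shock genes HSPA1B and HSPH1 were 5.87-fold and 5.34-fold higher, TUBA1B 9.96-fold and MCM5 3.49-fold. CXCL8 was 2.13-fold higher and GNLY 2.08-fold lower.

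Of 78 ribosomal protein genes, 45 were at least 2-fold higher in nonclassical monocyte-like cells, led by RPS19 (6.93-fold) and RPL36A (5.03-fold), while RPLP1 and RPL22 were 2.20-fold and 2.54-fold lower. MT-ATP6 and MT-CO2 were 6.68-fold and 5.50-fold higher, and of the respiratory chain genes COX6A1 was 7.97-fold and COX6C 5.82-fold higher and NDUFA11 2.05-fold lower. These values rest on the reference: without the largest classical monocyte-like cluster, 0 lists were higher and 4 lower, and the medians of the ribosomal protein and mitochondrially encoded lists turned to -1.04 and -0.08. In that setting 25 of 28 named ratios moved over 1.5 times, with OAS1 at a log2 ratio of 1.80, HSPA1B at 1.36 and HSPH1 at 1.19. Subtracting free RNA moved 9 of 29 named ratios over 1.5 times. Over 14 settings, the main setting included, 0 to 6 lists were higher and 0 to 4 lower. Of 30 named genes, 10 stayed past 2-fold on the same side in every setting that measured them: MCM5, HSPA1B, HSPH1, TNF, AREG, OAS1, CCR1, KLF2, TOX and LILRB1.

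**Figure D3:**
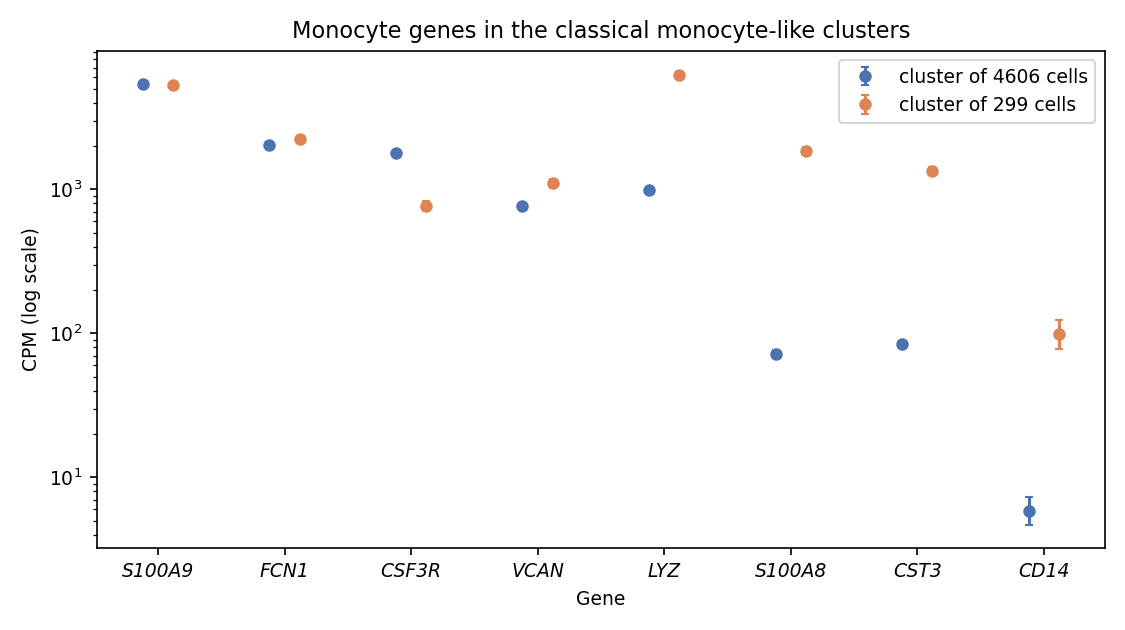
CPM (y axis, log scale) of 8 monocyte genes (x axis) in the 2 classical monocyte-like clusters of 4606 (blue) and 299 cells (orange), with exact Poisson 95% intervals as error bars. S100A9 is at 5391 and 5328 CPM, while S100A8 is at 72.2 and 1860 and CD14 at 5.86 and 99.1.

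The classical monocyte-like class held 2 unlike clusters, of 4606 and 299 cells, which differed in depth too: median UMIs were 2787.5 and 1526, genes 1616.5 and 925, mitochondrially encoded UMIs 2.32% and 3.05%, and ribosomal protein UMIs 4.27% and 10.6%. Both had S100A9 (5391 and 5328 CPM) and the lectin gene FCN1 (2028 and 2232 CPM), and the proteoglycan VCAN was at 764 and 1102 CPM. In the cluster of 4606 cells, S100A8, the partner of S100A9 in calprotectin, was at 72.2 CPM (95% interval 67.8 to 76.9), against 1860 (1761 to 1962) in the cluster of 299 cells. LYZ was at 990 against 6213 CPM, the cysteine protease inhibitor CST3 at 84.0 against 1345, and the lipopolysaccharide co-receptor CD14 at 5.86 against 99.1. CSF3R, the granulocyte colony-stimulating factor receptor, went the other way, at 1783 against 769 CPM.

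Conventional DC-like cells differed from classical monocyte-like cells first by antigen presentation: all 12 MHC class II genes were at least 2-fold higher (median 3.46), with HLA-DOA (ENSG00000204252) at 156 against 5.92 CPM (26.3-fold; log2 ratio 4.72, interval 4.38 to 5.07) and HLA-DQB1 15.4-fold higher. In all, 7 lists were higher, among them cell cycle on 2 measured genes, and 1, the Fc and complement receptors, lower (5 of 9 members lower; median -1.40). C5AR1, the receptor for complement C5a, was 13.4-fold lower and FCER2 3.78-fold lower, and FCGR2B was 23.0-fold higher. The growth factor AREG was 18.0-fold and IL18 5.83-fold higher, while TNF and TGFB1 were 2.63-fold and 2.16-fold lower and CXCL8 9.91-fold lower. The receptors LAIR1 and HAVCR2 were 4.06-fold and 2.07-fold lower. TAP2 and PSMB8 were 3.96-fold and 3.74-fold higher, and HLA-C was 2.10-fold lower. Immediate early genes split, NR4A1 being 2.35-fold higher and JUNB and JUN 2.42-fold and 2.07-fold lower. IRF7 was 2.38-fold higher and HERC5 2.73-fold lower. TUBA1B and MCM5 were 22.8-fold and 2.13-fold higher.

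Of 78 ribosomal protein genes, 64 were at least 2-fold higher in conventional DC-like cells (median 1.98), such as RPS2 (12.1-fold) and RPL36A (8.95-fold). COX6A1 and COX6C were 11.6-fold and 10.4-fold higher, MT-ATP6 and MT-CO2 6.29-fold and 4.72-fold, and HSPA8 and HSPE1 4.81-fold and 2.88-fold. Without the largest classical monocyte-like cluster, 2 lists were higher and 2 lower, and the ribosomal protein and mitochondrially encoded medians turned to -0.15 and -0.15. In that setting 23 of 27 named ratios moved over 1.5 times, with AREG going from 4.17 to 1.41 and HLA-DQB1 to 1.60. Subtracting free RNA moved 5 of 29 named ratios over 1.5 times. Over 14 settings, the main setting included, 2 to 8 lists were higher and 0 to 2 lower. Of 30 named genes, 13 stayed past 2-fold on the same side in every setting that measured them, among them HLA-DOA, HLA-DQB1, AREG, IL18, C5AR1 and CXCL8.

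**Figure D4:**
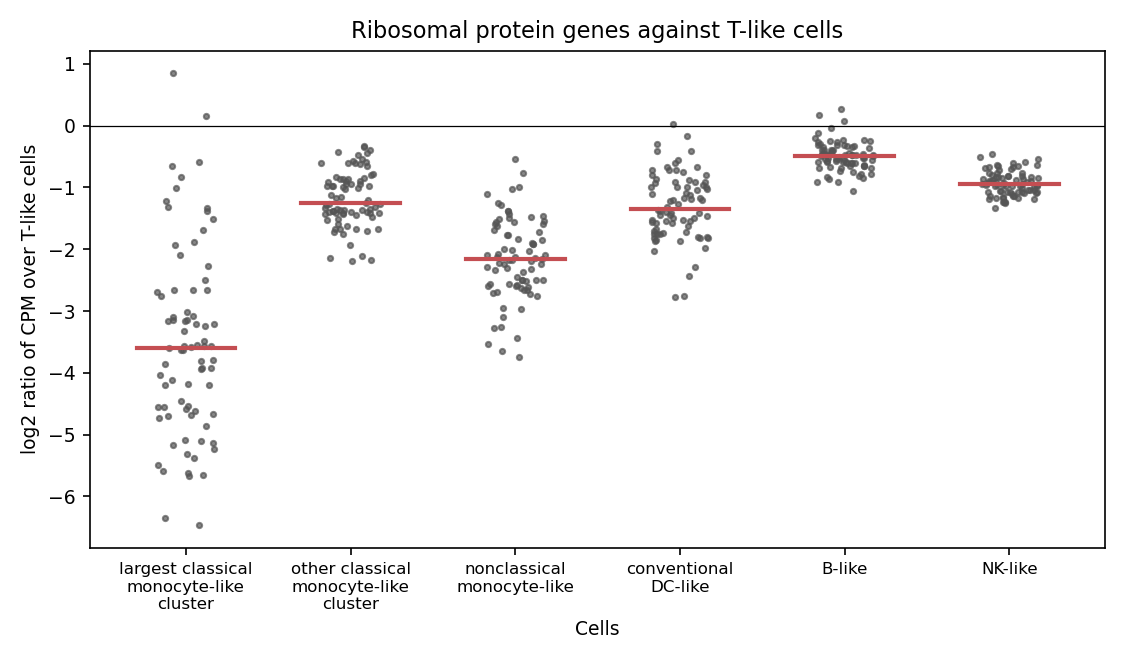
Log2 ratio of CPM over T-like cells (y axis) of each of 78 ribosomal protein genes (points) in 6 sets of cells (x axis), with medians as red lines. The largest classical monocyte-like cluster spans -6.46 to 0.85 around a median of -3.59, and NK-like cells span -1.33 to -0.46.

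Ribosomal protein genes were lowered unevenly in the largest classical monocyte-like cluster. Their log2 ratios over T-like cells had a median of -3.59 and an SD over genes of 1.53, from RPS18 at -6.46 to RPL22 at 0.85. In the other classical monocyte-like cluster the median was -1.26 and the SD 0.45, in nonclassical monocyte-like cells -2.16 and 0.66, in conventional DC-like cells -1.34 and 0.55, and in B-like cells -0.50 and 0.24. The unevenness was largest in that cluster but not particular to it. RPL22 was also the highest in nonclassical monocyte-like (-0.54) and conventional DC-like cells (0.03). The lowest there were RPS18 (-3.75) and RPS26 (-2.78).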

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

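The comparison of adult with embryonic and fetal globin below was chosen only after the result was seen.

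Signals in cells outside the compared classes stood above the limit that a count of 0 allows, which any detected gene of a cluster passes, so levels elsewhere stand beside them. In the unnamed cluster of 439 cells, IGHA1 was at 1437 CPM (limit 1.28; 2.06 elsewhere), beside IGHG4 at 523 CPM, JCHAIN at 697 CPM and the B-cell gene MS4A1 at 769 CPM. In the unnamed cluster of 260 cells with the lowest ribosomal protein share (median 0.836%), the noncoding RNA NEAT1 was at 9444 CPM (limit 4.28; 1373 elsewhere), beside the membrane-repair gene DYSF at 164 CPM and CSF3R at 1620 CPM. In the unnamed cluster of 189 cells, with a median of 4858 UMIs and 2473 genes, BCL11B, a T-cell transcription factor, was at 655 CPM (limit 2.81; 18.5 in the largest classical monocyte-like cluster and 652 in T-like cells) while S100A9 was at 2171 CPM, and a mixture of cells was not tested.

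In 24 cells (0.132%), HBG1, HBG2 and HBE1, the fetal and embryonic globins, together reached 11406 CPM (95% interval 10448 to 12427; limit 65.5), with PRAME, a cancer-testis gene, among the leading genes. Erythroid precursors of the donor are argued against by adult globin UMIs (HBB, HBA1 and HBA2), which were 3.83% of the fetal and embryonic ones. A limit is that HBB was at only 19.0 CPM in platelet-like barcodes, where HBA1 was at 503 CPM. How fully this library counts HBB was not tested. For free RNA or a barcode shared with donor cells, CD3E, MS4A1 and S100A9 together had to reach at least 50% of their level over all cells. They stood at 9.09% (interval 3.34 to 19.8, on 6 UMIs), which argues against barcodes filled by free RNA with the mean makeup of all cells. Free RNA with less S100A9 is not decided. In T-like cells S100A8 and S100A9 were at 16.8 and 37.7 CPM, against 160 and 5388 in classical monocyte-like cells, so the background had another makeup. A barcode shared with a T-like cell is not decided either, since T-like cells themselves held CD3E, MS4A1 and S100A9 together at 393 CPM against 1442 over all cells. Set against T-like cells, the level in the 24 cells was 33.3%. A candidate source is cells of an erythroleukaemia line such as K562: HBZ and GAGE genes, listed before the test, were at 1093 CPM on 50 UMIs against 2.33 in T-like cells, where at least 50 CPM was required. These genes alone do not settle the identity, which rests on 24 cells, and GAGE copies share reads.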

How the results depend on the processing

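The tests with the immunoglobulin-led cluster as B-like, without the largest classical monocyte-like cluster, with the GZMH-led cluster in the CD8 T-like class and with the other doublet implementation were chosen only after the results were seen. Of the gene ratios under the planned settings, 1515 stayed within the 95% counting interval, 283 left it in the same direction and 1 reversed; under the added settings the numbers were 201, 77 and 31. For list medians they were 926, 380 and 10 (planned) and 128, 81 and 11 (added), with intervals from 200 Poisson redraws and a reversal counted only for medians at least 2-fold from 0. Past 2-fold on the same side in every setting that measured them were 28 of 30 named genes for classical monocyte-like over T-like cells, 29 of 30 for B-like, 27 of 30 for NK-like, 6 of 23 for CD8 over CD4 T-like, 10 of 30 for nonclassical and 13 of 30 for conventional DC-like cells. A setting that did not measure a gene could not test it. For CD8 over CD4 T-like cells, resolution 0.5 measured 8 of the 23 named genes. T-like shares ranged from 44.8% to 47.8% over 9 settings. The causes of the changes below were not tested unless stated. Small classes limit the depth, so that genes under 20 UMIs in both classes were not read. No paired analysis was possible because the labels hold 1 library per technology and the results come from no test.

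The stricter cell filter gave shares of 44.8% T-like, 2.76% NK-like, 14.97% B-like and 28.1% classical monocyte-like cells, and the immunoglobulin-led cluster as B-like gave 16.03%, by construction. Without thinning the ratio of genes per cell was 1.01. CPM without the abundant genes gave 4 higher lists for classical monocyte-like over T-like cells, 3 higher and 2 lower for NK-like cells and 3 lower for CD8 over CD4 T-like cells, and turned the inhibitory receptor list of classical monocyte-like over T-like cells to -0.47. Median-of-ratios scaling gave 4 higher lists for classical monocyte-like and 2 lower for NK-like over T-like cells. For CD8 over CD4 T-like cells, resolution 0.5 gave 1 lower list and turned MIAT to 0.48 and the cytotoxic list to 0.67, resolution 2 gave 2 lower lists and turned the cell cycle list to 0.13, and function lists among the variable genes gave 3 lower. Subtracting free RNA gave 1 lower list for NK-like over T-like cells and moved 23 of 30 named ratios of classical monocyte-like, 13 of 30 of B-like and 7 of 30 of NK-like over T-like cells by over 1.5 times, 8 of 22 of CD8 over CD4 T-like, 9 of 29 of nonclassical and 5 of 29 of conventional DC-like cells. The mean over cells gave 3 higher lists for nonclassical over classical monocyte-like cells, 3 lower for CD8 over CD4 T-like and 2 lower for conventional DC-like cells.

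With a minimum of 10 UMIs and 1 CPM, which reads more genes, 1 list was higher for B-like over T-like cells, 2 higher and 1 lower for NK-like, 2 higher and 1 lower for nonclassical and 0 lower for conventional DC-like cells. It turned the Fc and complement receptor list of CD8 over CD4 T-like cells to 0.12, the cytokine list of conventional DC-like cells to -0.24, and the inhibitory receptor list to -0.67 for NK-like and -1.13 for classical monocyte-like over T-like cells. With 50 UMIs and 50 CPM, 4 lists were higher for B-like over T-like cells, 1 lower for CD8 over CD4 T-like and 2 lower for conventional DC-like cells; the receptor list of B-like cells turned to 1.99, the cytokine list of conventional DC-like cells to -0.24 and the cytotoxic list of CD8 over CD4 T-like cells to 0.71.

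With the GZMH-led cluster in the CD8 T-like class, 4 lists were higher and 0 lower, and these log2 ratios turned: CCL5 3.15, CGAS 0.011, CST7 3.65, GZMK 0.81, HLA-DPA1 1.87, HLA-DRB1 1.11, IFIT1 0.53, IFIT3 1.32, KLRG1 2.78, MIAT 1.49, PRDM1 0.50, TNF 0.12 and TOX 0.47. So did the lists of Fc and complement receptors (0.37), MHC class II (1.16), chemokines (3.95) and cytotoxic granules (3.65). Without the largest classical monocyte-like cluster, 6 lists were lower for classical monocyte-like over T-like cells, with STING1 at 0.66. For nonclassical cells 0 lists were higher and 4 lower, with COX6A1 at -0.74, COX6C -0.65, CXCL8 -1.15, CXCR4 -0.32, HLA-F -0.66, MT-ATP6 -0.16, RPL36A -1.05 and TUBA1B -0.061, with the median log2 ratio of the heat shock list, nonclassical monocyte-like over classical monocyte-like, at -0.0011, and lists of cytokines at -0.49, mitochondrially encoded -0.080 and ribosomal protein genes -1.04. For conventional DC-like cells 2 lists were higher and 2 lower, with COX6A1 at -0.20, HAVCR2 0.28, HSPA8 -0.027, HSPE1 -0.13, IRF7 -0.56, MT-ATP6 -0.25, MT-CO2 -0.13, PSMB8 -0.21 and RPL36A -0.22, and lists of cytokines at -0.47, mitochondrially encoded -0.15 and ribosomal protein genes -0.15.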

Other observations

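The coding sequence, MALAT1, between-cluster, free S100A8, free RNA and doublet tests below, and the choice of the T-like clusters and of the HFM1 genes described here, were made only after the result was seen.

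The T-like clusters differed in the function lists when each was set against the other T-like cells. The GZMH-led cluster of 1226 cells, with CD8A at 396 CPM and NKG7 at 3088 CPM, had 10 of 11 cytotoxic granule genes at least 2-fold higher (median log2 ratio 2.39) and all 9 measured MHC class II genes (2.06). A cluster of 736 cells with TRDC, a γδ receptor constant region, at 396 CPM had 12 of 18 interferon-stimulated genes higher (1.78), with IFIT2 at 1953 CPM, and all 5 measured chemokines (3.27), with TNF at 415 CPM. MAIT-like cells, with KLRB1 at 2240 CPM and the transporter SLC4A10 at 273 CPM, had 3 of 5 chemokine and sphingosine receptors higher (1.86) and MHC class II genes lower (-1.32). Treg-like cells, with FOXP3 at 53.5 CPM, IL2RA at 179 CPM and CTLA4 at 144 CPM, had 5 of 8 MHC class II genes higher (1.05) and 10 of 11 cytotoxic granule genes lower (-4.27).

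Most classical monocyte-like cells had low S100A8, CD14, LYZ and CST3 beside high S100A9 and FCN1, and an uneven lowering of ribosomal protein genes. The sequence tests used the log2 ratio of the whole classical monocyte-like class, both clusters together, over T-like cells. Over the 78 ribosomal protein genes, that ratio had a partial Spearman rho of 0.115 with coding length given UpA number (95% interval -0.13 to 0.34, plain rho 0.017, whole annotated transcripts 0.096). This argues against greater loss of longer RNA among these genes, while greater loss of shorter RNA was not tested. Loss by UpA dinucleotides stays open, at a rho of -0.098 with their number in the coding sequence (-0.31 to 0.12, whole transcripts 0.031). Neither test covers S100A8, CD14, LYZ or CST3. Loss of cytoplasm that leaves nuclei is argued against by MALAT1 at 0.418 times the nonclassical and 0.261 times the other classical monocyte-like level (3991 against 9551 and 15275 CPM, 0.327 of T-like), unless the same loss reached MALAT1. This rests on a single nuclear RNA. The median mitochondrially encoded share was 2.32% in the largest cluster, against 2.74% in nonclassical cells and 3.05% in the other classical cluster, a direction that such loss would also give. As to the authors' counting, LYZ, S100A8 and CD14 were each at least 6.27 times higher in the other cluster, which they lead. That difference is part of the pattern itself, so it shows only that these genes could be counted in this library. S100A8 per S100A9 was 33.1 times higher in T-like cells (0.444), where both are free RNA, than in that cluster (0.0134), so the state may have arisen after that RNA was released, or the free RNA came from cells like the other cluster (0.349). The cause is open, and no biological explanation was tested because the design gives no group for it.

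HFM1 (chromosome 1: 91260766-91404869, GENCODE 29 on hg38), a meiotic helicase gene, was at 589 CPM in a T-like cluster of 320 cells and 584 CPM in a B-like cluster of 99 cells, against 14.7 and 10.5 CPM elsewhere in those classes and 58.4 CPM in NK-like cells. LRFN5 on chromosome 14 (436 and 473 CPM) and NYAP2 on chromosome 2 (150 and 156 CPM) went with it. Free RNA spread evenly over cells is argued against by a variance over mean of 12.8 across 453 NK-like cells for 9 genes that lead the T-like cluster, where under 1.5 was required; earlier forms over T-like and B-like cells (6.73 in the latter) were void, as those cells include the clusters described. Doublets with another cell type are argued against by a ratio of median UMIs of at most 1.10 over the other clusters of the class. The source could not be told from these counts, and no biological explanation was tested.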
